A study of Rattus norvegicus with 4 samples.

How the data were processed

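RNA from 4 rat bone marrow cell cultures was measured on Agilent one-colour arrays, on which Cy3-labelled copies of total RNA bind to printed probes. The cells came from Wistar rats aged 6 weeks and were grown for 15 days at high density on 2 arrays and at regular density on 2 arrays. The sources used here describe 2 independent experiments. They do not say whether a replicate number marks the same experiment in both groups, so the groups were compared without pairing. Seeding numbers, media and the source of each culture's marrow are not given in the sources used here.

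The deposited spot table holds intensity on a linear scale, per the file headers the signal left after all steps of the scanner software. The submitters' processing notes name that software as Agilent Feature Extraction 11.0.1.1. The spot table holds 44254 spots per array, of which 1377 were control spots, and no detection flags. The authors also deposited a table of 21473 probes with raw intensity, in which spots of a probe were combined and values under 5 were set to 5, and with normalized log2 values. Those normalized log2 values, deposited by the authors, have nearly one distribution on all 4 arrays, and the deposited series matrix holds the same log2 values. GeneSpring GX is named by the authors in the header of the spot table, but the normalization method and the rule that left out 8894 probes are not given in the sources used here.

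Control spots were left out and the log2 intensities of repeated spots were averaged, which gave 30367 probes, 28977 printed once and 1390 printed 10 times. Each array was scaled by subtracting the 75th percentile of its log2 intensity and adding back the mean of these percentiles. Intensities at or under 0 were to be set to 1. A probe was tested when its mean log2 value over all 4 arrays was above 5.62, the median of all probes, whatever its group. The probe with the highest mean stood for its gene. Symbols were updated through Entrez gene IDs or RefSeq accessions, since 25 symbols in the authors' table had been turned into dates by a spreadsheet. Of the probes, 12297 kept a symbol that matched the reference, 3413 had it updated, 1013 kept one whose ID was not in the reference, 4821 were named through an accession and 8823 stayed unnamed. Probe positions are those in the authors' table, which names no genome assembly.

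The groups were compared with limma 3.58.1 in R 4.3.3, by a linear model with moderated variances that follow the trend with mean intensity, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The design left 2 residual degrees of freedom, to which the moderation added 4.43. The p-values measure only the spread between these samples. Gene lists were tested against all other features with limma's camera at a preset correlation of 0.01 between genes, for lists with at least 5 tested members. Camera with an estimated correlation and limma's fry, which asks whether the genes of a list move on balance in one direction, stand beside it. With 2 residual degrees of freedom the estimated correlation is imprecise, so the preset correlation was the main setting. Unless stated otherwise, list sizes in the results count tested genes only, without members too dim to test. A count of features that differed by a fold of 2 or more in every pair of a high density and a regular density array was added as a description without a test.

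Background was taken as the 99th percentile of the 153 negative control spots of each array. Where a gene lay under it on both arrays of a group, the fold is given as a lower bound against that background. The number of arrays, 2 per group, limits the precision. For comparison with brightness alone, each list was set beside 10000 random lists of the same size, drawn from 50 bins of mean intensity.

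The grouping, the tests, the 35 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule names the 10 largest rises and the 10 largest falls among genes with a symbol, past the threshold and above background on both arrays of the brighter group. It adds up to 4 members with the smallest p from each list, any reference gene, and Pecam1, Cdh5, Kdr, Vwf, Cd34, Prom1, Cd14 and Ptprc whatever their values. The alternatives fixed in advance were quantile, median and no scaling, a floor of 32 on intensity, the authors' normalized values and the series matrix, no filter on dim probes and a stricter one (mean above 7.59). Further ones were the mean over a gene's probes, other variance models, an unmoderated test, a fold of at least 2, a replicate block and leaving out each array. Filters on the authors' probes and on the negative controls, cyclic loess, leaving out olfactory receptor genes with unnamed probes, and leaving out each array in the count over pairs of arrays were added after seeing the data.

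The method was tested on 20 simulated sets of the comparison of high with regular density, each with 13683 features of which 200 were changed. It recovered 3.38% of features changed by a fold of 1.41, 65.4% of those changed by a fold of 2 and 93.1% of those changed by a fold of 4. Of the calls, 4.1% were false and 0 had the wrong sign. In sets without any change, 2 features and 0 of 640 lists were called over all 20 sets. Features were simulated independently of each other, with variances drawn from the fitted model. These rates therefore do not cover correlation between genes or deviations shared by arrays, and cannot decide how many list calls in the data are false. Each set had 200 changed features, whereas 4233 were called in the data. The Benjamini-Hochberg adjustment was thus stricter in the simulated sets, and the recovered shares do not carry over to the data.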

Results

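Gene expression was measured in cultured rat bone marrow cells, which the submitters call endothelial progenitor cells, after 15 days at high density (2 arrays) or regular density (2 arrays). The 75th percentile of probe intensity was 386 and 462 on the high density arrays and 355 and 435 on the regular density arrays. Of 30367 probes, 54.8% and 61.2% lay above background on the high density arrays, and 53.9% and 55.7% on the regular density arrays. The median negative control spot read 13.4 and 1.93 on high density replicates 1 and 2, and 10.5 and 1.99 on regular density replicates 1 and 2, so the background floor split the arrays by replicate number. Medians within each replicate number are therefore given beside the values of the main lists. Pearson's r across the 13683 tested features was 0.993 within each group and 0.959 to 0.975 between groups. Features are not independent replicates. Over the same features, the median absolute difference was 0.12 log2 between the high density arrays, 0.17 between the regular density arrays and 0.29 between the group means.

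The comparison asks how gene expression after high density culture differs from that after regular density culture. After high density culture, genes of the smooth muscle contractile apparatus rose most, led by the smooth muscle actin Actg2, which was 91.7-fold higher (log2 change 6.52, SE 0.11, n = 2 arrays per group), and the smooth muscle myosin heavy chain Myh11, which was 36.2-fold higher (log2 change 5.18, SE 0.09). Genes of cell division also rose together, with a median log2 change of 1.54 over 28 genes, among them Ccnb1, the cyclin of mitotic entry. The metal-binding metallothioneins Mt2A and Mt1 fell, with log2 changes of -3.80 (SE 0.10, adjusted p = 3.03e-05) and -3.50 (SE 0.10). By smaller amounts, 15 of 17 glycolysis genes, 15 of 19 genes of the response to low oxygen, 22 of 28 lysosome genes and 16 of 23 genes of unfolded protein and amino acid stress fell. Each of these lists was called lower with a preset correlation, and each had adjusted p = 0.254 with an estimated correlation. For cell division that value was 0.220. The endothelial markers Pecam1, Kdr and Cd34 were too dim on average to test. Over the 13 endothelial genes tested, the median was 0.42. That list was called higher with a preset correlation (adjusted p = 0.00868) and had adjusted p = 0.374 with an estimated correlation.

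Of 13683 features tested, 1780 were higher and 2453 lower at high density at an adjusted p under 0.05 with limma. Named genes made up 1367 of the higher and 1592 of the lower features, and unnamed probes the other 413 and 861. A fold of 2 or more as well was reached by 635 higher and 233 lower features, of which 468 and 184 were named genes. The 2 groups did not overlap for 69.7% of features, where chance gives 33.3% on average over the ways to split the arrays. Features share deviations of whole arrays, so the gap between these shares is a description and was not tested. Without high density replicate 1 the number of changed features was 2412, and without any scaling it was 1971, of which 1393 were higher and 578 lower. The median change of all features was -0.08, and it moved to -0.20 under median scaling and to 0.03 without scaling, so changes near 0 depend on the scaling.

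Among the 10 largest rises, Cnn1, which encodes the smooth muscle protein calponin, was at least 16.7-fold higher (adjusted p = 8.51e-05), since it lay under background on both regular density arrays. Mylk, the kinase that activates smooth muscle myosin, was 34.1-fold higher (log2 change 5.09, SE 0.32, adjusted p = 2.53e-04). The integrin subunit Itga8 rose by 4.36 log2, with 1 of 2 regular density arrays above background. Pln, the phospholamban that restrains the calcium pump of muscle, rose 15.7-fold, and the skeletal muscle actin Acta1 rose 14.2-fold. The matrix protein gene Spon1 was at least 5.59-fold higher and Spink8, of the family of serine protease inhibitors, at least 5.35-fold higher. Il1rl1, the receptor for interleukin-33, rose 12.6-fold.

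Among the 10 largest falls, the melanosome protein gene Pmel was at least 8.91-fold lower at high density, and Apln, which encodes the vascular peptide apelin, at least 7.39-fold lower. Both lay under background on both high density arrays. Clic2, of the chloride intracellular channel family, was at least 4.91-fold lower. Akr1c15, of the aldo-keto reductases, had a log2 change of -3.68, and Prg4, the joint lubricant lubricin, one of -3.37. The matrix protein gene Comp had a log2 change of -3.09 (SE 0.12), the complement component C3 one of -2.72 (SE 0.19) and Enpp2, the enzyme autotaxin that makes lysophosphatidic acid, one of -2.71 (SE 0.41). Of these, Akr1c15, Prg4 and Enpp2 lay above background on 1 of 2 high density arrays. In the authors' table, whose assembly is not named, the probes of Actg2 (Entrez gene 25365) and Myh11 (Entrez gene 24582) lie on chromosome 4 from 117732483 to 117732542 and on chromosome 10 from 775993 to 776052. Those of Mt2A (Entrez gene 689415) and Mt1 (Entrez gene 24567) lie on chromosome 19 from 11267834 to 11267893 and from 11261631 to 11261690.

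**Figure D1:**
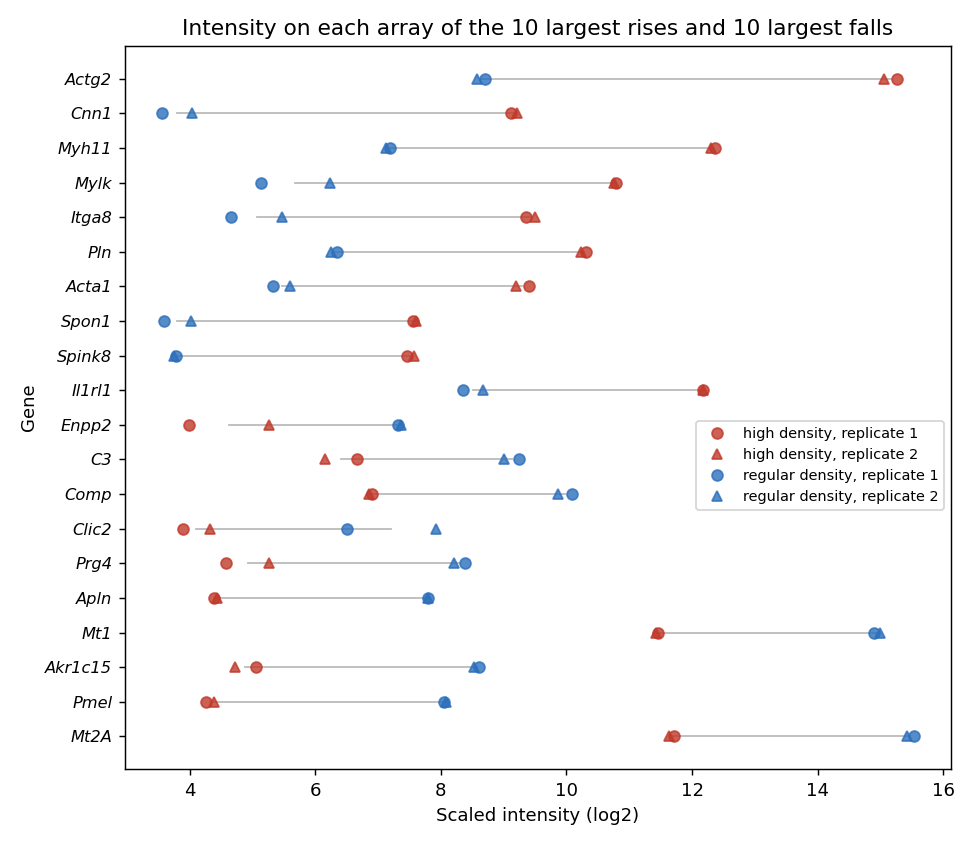
Scaled log2 intensity (x axis) of the genes with the 10 largest rises and the 10 largest falls (y axis) on each of the 4 arrays. Red points are high density arrays and blue points regular density arrays, circles and triangles mark replicates 1 and 2, and grey lines join the group means. Actg2 had a log2 change of 6.52 and Mt2A one of -3.80.

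Of 14 tested smooth muscle and contractile genes, 13 rose and 0 fell, both over all genes and adjusted over the list alone. The list median was 2.82, or 2.80 and 2.84 within replicate numbers 1 and 2, and it stayed at 2.82 with Cnn1 at its lower bound. The list was called higher (adjusted p = 6.95e-15), with adjusted p = 0.220 with an estimated correlation. Besides the genes above, the regulatory myosin light chain Myl9 rose by 3.36 log2 and the smooth muscle alpha-actin Acta2 by 3.06. Probes for actins can bind the RNA of related actins.

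Of 28 cell division genes, 27 rose over all genes and 28 adjusted over the list alone. The list median was 1.54, or 1.62 and 1.51 within replicate numbers 1 and 2 (adjusted p = 4.03e-20, and adjusted p = 0.220 with an estimated correlation). Cdca3, which promotes entry into mitosis, rose by 2.11 log2, the spindle motor Kif20a by 2.07, Ccnb1 by 1.97 and Ube2c, the enzyme that tags cyclins for destruction, by 1.87. Of 23 DNA replication genes, 16 rose over all genes and 20 adjusted over the list alone, with a median of 0.49, or 0.53 and 0.51 within replicate numbers 1 and 2. That list was called higher (adjusted p = 6.77e-09), with adjusted p = 0.222 with an estimated correlation. Rrm2, a subunit of the enzyme that makes deoxynucleotides, rose by 1.57, Gins1, part of the replicative helicase, by 1.41 and the helicase subunit Mcm4 by 0.79. Among 21 p53 targets and genes of cell cycle arrest, 7 fell over all genes and 8 adjusted over the list alone, while 0 rose. Its median was -0.25 (adjusted p = 0.0274, and adjusted p = 0.254 with an estimated correlation), within the range of random lists of like brightness, and ran from -0.37 to -0.14 over the alternatives. The DNA damage gene Gadd45a had a log2 change of -1.67, the cell cycle inhibitors Cdkn2b and Cdkn2a changes of -1.10 and -1.05, and the p53 inhibitor Mdm2 one of -0.86.

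Of 30 endothelial cell genes on the array, 13 were bright enough to test. Of these 13, 5 rose and 1 fell, both over all genes and adjusted over the list alone. The median was 0.42, or 0.60 and 0.24 within replicate numbers 1 and 2, and 0.20 without high density replicate 1. It was called higher (adjusted p = 0.00868), with adjusted p = 0.374 with an estimated correlation. The adhesion molecule Mcam, which vascular smooth muscle also carries, rose by 2.33, the VEGF receptor Flt1 by 1.59 and Egfl7, an endothelial secreted protein, by 0.66, whereas thrombomodulin, Thbd, fell by 0.76. With a stricter filter on dim probes (mean above 7.59) the call ended (adjusted p = 0.0569, where the alternatives within camera at the preset correlation ranged from 0.00484 to 0.0569), as it did with fry (adjusted p = 0.0713). VE-cadherin, Cdh5, had a log2 change of 0.42 (adjusted p = 0.108) and von Willebrand factor, Vwf, one of 0.09 (adjusted p = 0.870). With each array left out, the change of Vwf ranged from -0.40 to 0.59. Pecam1 lay above background on 0 high density arrays and 1 regular density array, Kdr on 1 and 0, and Cd34 on 0 and 0. Prom1, which encodes the progenitor marker CD133, lay above background on both high density arrays (log2 values 6.13 and 6.40) and on 0 regular density arrays (3.72 and 4.25), but was too dim on average to test.

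Among 11 genes of blood and endothelial progenitor cells, 4 rose and 1 fell by either adjustment, and the list was not called (median 0.08, adjusted p = 0.398). Leaving out each array moved that median from -0.06 without regular density replicate 1 to 0.23 without regular density replicate 2, with -0.05 without high density replicate 2 and 0.22 without high density replicate 1. Over all alternatives the median ran from -0.07 to 0.50. The chemokine receptor Cxcr4 rose by 0.60, a call that ended without high density replicate 1 (0.51), and the transcription factor Mycn had a log2 change of -1.75. Of 26 monocyte and macrophage genes, 7 rose and 1 fell by either adjustment, with a median of 0.16, or 0.18 and 0.19 within replicate numbers. As a whole it was called higher (adjusted p = 0.00309, and adjusted p = 0.254 with an estimated correlation), and its median was 0.08 without high density replicate 1, 0.03 under median scaling and 0.31 under cyclic loess. The complement genes C1qa, C1qc and C1qb, which macrophages make, rose by 2.77, 2.49 and 1.71. The monocyte marker Cd14 had a log2 change of -0.38 (adjusted p = 0.0487), a call that ended under quantile scaling (-0.26) and without high density replicate 1 (-0.41), high density replicate 2 (-0.34) or regular density replicate 1 (-0.26). The leukocyte marker Ptprc had a log2 change of 0.03 (adjusted p = 0.842).

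Of 9 genes of antigen presentation by MHC class II, 4 rose and 0 fell by either adjustment, and the list was called higher (median 0.17, adjusted p = 0.00426, and adjusted p = 0.254 with an estimated correlation). Its median was 0.25 without high density replicate 1 and 0.04 under median scaling, and lay within the range of random lists of like brightness. The class II chain RT1-Da rose by 1.24 and its chaperone Cd74 by 0.98. Of 27 lymphocyte genes on the array, 7 were bright enough to test. Of these 7, 5 rose and 0 fell by either adjustment, with a median of 1.12, or 1.01 and 1.08 within replicate numbers. The list was called higher (adjusted p = 3.69e-05, and adjusted p = 0.254 with an estimated correlation). The protease Gzmb of cytotoxic cells rose by 2.88, the T cell coreceptor chains Cd8a and Cd8b by 2.48 and 1.15, and the B cell adaptor Blnk by 1.12. With no filter on dim probes the median of that list was 0.08.

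The osteoclast list was not called (8 genes, adjusted p = 0.939), with 0 genes changed by either adjustment and a median of -0.10, although the test's direction was upward. Its median was -0.07 to -0.03 with each array left out. Of 5 red cell genes, 2 rose by either adjustment, and the list was not called (median 0.25, adjusted p = 0.0561), except without regular density replicate 1 (0.38; without regular density replicate 2 it was 0.12) and without a variance trend, among others (adjusted p from 0.0377 to 0.154 over the alternatives). Granulocytes, mast cells and basophils, and megakaryocytes and platelets had 3, 1 and 3 tested genes, too few for a list test. In the order of those lists, the collagenase Mmp8 rose by 1.71, Il1rl1 by 3.66 and the platelet glycoprotein Gp1bb by 0.75. The other 2 granulocyte genes and the other 2 megakaryocyte genes did not pass the test, with log2 changes from -0.27 to 0.54.

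Of 27 stromal cell and fibroblast genes, 9 rose and 6 fell over all genes, and 10 rose and 6 fell adjusted over the list alone. The list was not called (median 0.09, adjusted p = 0.0552), but it was called higher under quantile scaling (median 0.34, adjusted p = 7.07e-04, where the alternatives ranged from 6.9e-04 to 0.0887) and without regular density replicate 1 (median 0.12). Other alternatives that called it higher included no scaling, the authors' values, no filter on dim probes, the stricter filter, cyclic loess and fry (adjusted p = 0.0308 with fry). The chemokine Cxcl12 rose by 2.04, the ectonucleotidase Nt5e by 1.57 and the matrix protein gene Tnc by 1.48, whereas the proteoglycan gene Dcn fell by 1.34. Of 9 osteoblast genes, 5 rose and 0 fell by either adjustment, and the list was called higher (median 0.46, adjusted p = 0.0154, and adjusted p = 0.370 with an estimated correlation). Its median ranged from 0.23 with no filter on dim probes to 0.95 with the stricter filter. The bone transcription factor Dlx5 rose by 1.55, the alkaline phosphatase Alpl by 1.46 and Tnfrsf11b, the osteoclast inhibitor osteoprotegerin, by 1.29. Of 10 adipocyte genes, 5 rose and 1 fell by either adjustment, and the list was called higher (median 0.39, adjusted p = 0.0410, and adjusted p = 0.258 with an estimated correlation). Its adjusted p ranged from 0.012 to 0.105 over the alternatives. The call ended under quantile scaling (0.0646), without scaling (0.0858), with the authors' values (0.0657), with the stricter filter (0.105) and under cyclic loess (0.0815). It also ended without either high density array or regular density replicate 1, which gave medians of 0.36, 0.43 and 0.36. The fat cell regulator Pparg rose by 1.08 and the fatty acid carrier Fabp4 by 0.80. Of 6 chondrocyte genes, 2 rose and 1 fell over all genes, and 3 rose and 1 fell adjusted over the list alone. That list was not called (median 0.44, mean -0.01, adjusted p = 0.174, the median being 0.23 without high density replicate 1), with an upward test direction, a rise of 1.36 for the cartilage regulator Sox9 and a change of -3.09 for Comp.

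Brighter features had lower changes as a whole: the median was 0.13 for 869 features with a mean log2 value under 6 and -0.39 for 584 features above 14. Of the 20 lists called, 16 lay outside the range of random lists of like brightness in their direction. Of 17 glycolysis genes, 0 rose and 15 fell by either adjustment, with a median of -0.57, or -0.62 and -0.53 within replicate numbers. Together they were called lower (adjusted p = 1.61e-06, and adjusted p = 0.254 with an estimated correlation). The enolase Eno2 had a log2 change of -1.18, the aldolase Aldoc one of -0.93 and the kinase Pgk1 one of -0.77, which was -0.48 under quantile scaling. Of 19 genes of the response to low oxygen, 15 fell over all genes and 16 adjusted over the list alone, with a median of -0.69, or -0.78 and -0.63 within replicate numbers. That list was called lower (adjusted p = 3.16e-06, and adjusted p = 0.254 with an estimated correlation). The lipase inhibitor Angptl4 had a log2 change of -1.73, the vascular peptide adrenomedullin, Adm, one of -1.38, the mitophagy receptor Bnip3 one of -1.26 and the mTOR inhibitor Ddit4 one of -1.25. Of 34 oxidative phosphorylation genes, 1 rose and 0 fell over all genes and 0 changed adjusted over the list alone, and the list was not called (median -0.12, or -0.07 without regular density replicate 2, adjusted p = 0.546). Its direction was reversed under quantile scaling and cyclic loess (medians 0.01 and 0.06).

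Of 23 genes of unfolded protein and amino acid stress, 1 rose and 16 fell by either adjustment, with a median of -0.53, or -0.51 and -0.61 within replicate numbers. The list was called lower (adjusted p = 7.83e-04, and adjusted p = 0.254 with an estimated correlation). The stress transcription factor Ddit3 had a log2 change of -2.06, and the endoplasmic reticulum chaperones Pdia4 and Hsp90b1 had changes of -1.14 and -1.13. Of 20 genes of the oxidative stress response by Nrf2, 1 rose and 9 fell by either adjustment, and the list was called lower (median -0.22, adjusted p = 0.00512, and adjusted p = 0.254 with an estimated correlation). Its median lay within the range of random lists of like brightness and ran from -0.34 to -0.08 over the alternatives. The glutathione transferase Gsta1 had a log2 change of -1.99, the quinone reductase Nqo1 one of -1.66 and the aldehyde oxidase Aox1 one of -1.63.

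Of 28 lysosome genes, 1 rose and 22 fell over all genes, and 1 rose and 24 fell adjusted over the list alone. The median was -0.55, or -0.61 and -0.50 within replicate numbers, and -0.36 under quantile scaling. That list was called lower (adjusted p = 1.42e-06, and adjusted p = 0.254 with an estimated correlation). The lysosomal channel Mcoln1 had a log2 change of -1.32, the glucosidase Gaa one of -1.09, the protease Ctsh one of -1.08 and the membrane protein Lamp1 one of -0.92. Of 34 cytosolic ribosomal protein genes, 0 rose and 22 fell over all genes, and 27 fell adjusted over the list alone. Their median was -0.43, or -0.45 and -0.40 within replicate numbers (adjusted p = 1.42e-06, and adjusted p = 0.254 with an estimated correlation), with Rps18 at -0.75 and Rpl13 at -0.71. Random lists of like brightness ranged from -0.43 to -0.26. Under quantile scaling the median was -0.13, and under cyclic loess, which removes trends with brightness, it was -0.09 and the call ended (adjusted p = 0.0751, where the alternatives ranged from 4.01e-11 to 0.0751). Of 15 reference genes of uniform use, 2 rose and 3 fell over all genes, and 2 rose and 6 fell adjusted over the list alone. The list was not called (median -0.15, adjusted p = 0.515), and its direction was reversed under quantile scaling and cyclic loess (medians 0.01 and 0.04). Without regular density replicate 1 the median was -0.04. Among them the cytoskeletal actin Actb rose by 0.70, whereas Pgk1 had a log2 change of -0.77.

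**Figure D2:**
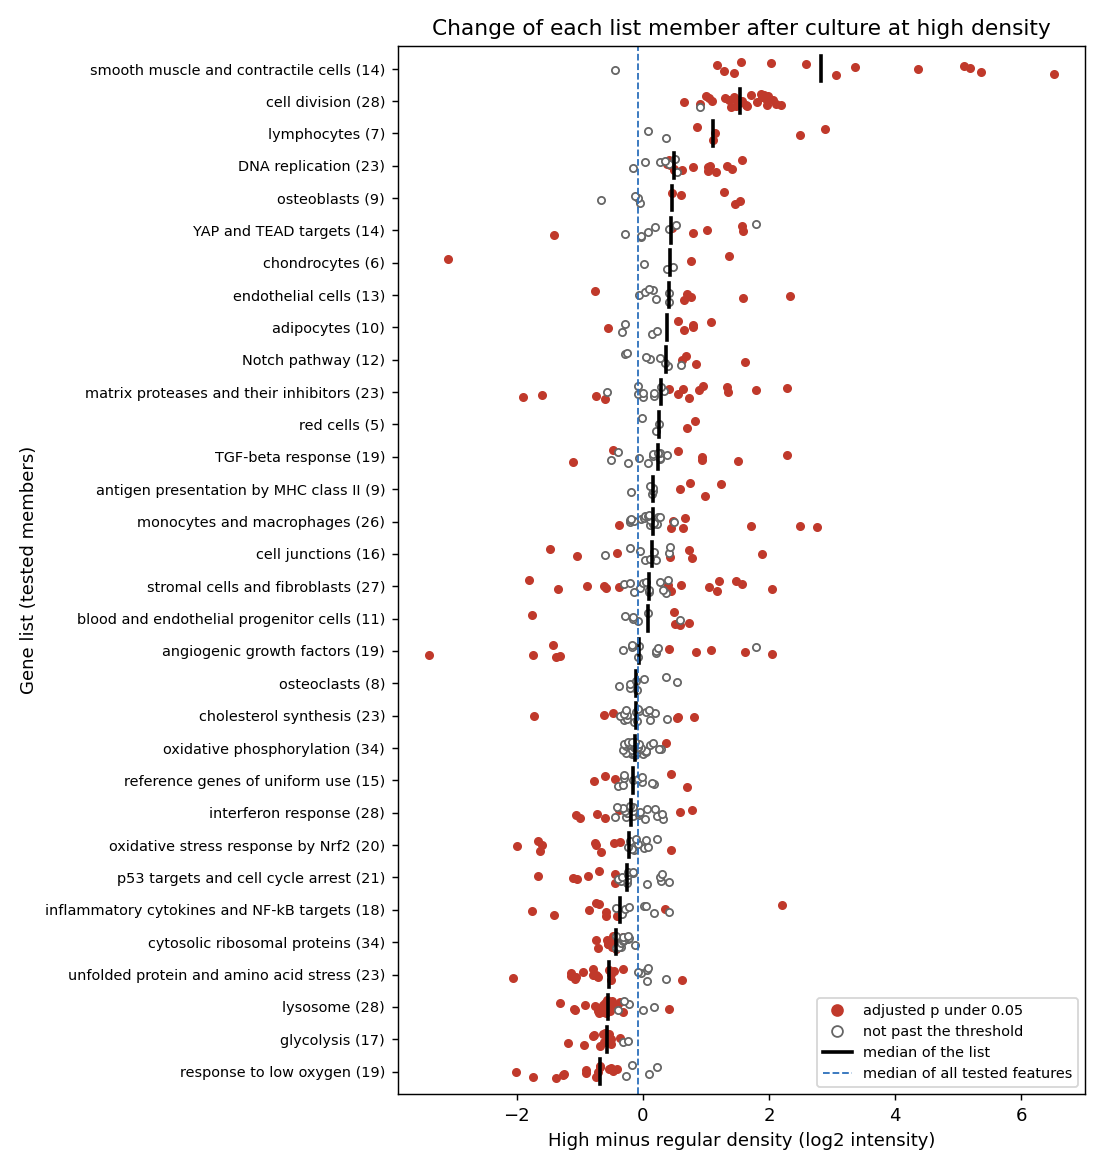
Log2 change from regular to high density (x axis) of each tested gene in the 32 tested lists (y axis, with the number of tested genes), with filled points for genes past the threshold, black bars for list medians and a dashed line for the median of all features. The medians ran from 2.82 for smooth muscle genes to -0.69 for the response to low oxygen.

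Of 18 inflammatory cytokines and NF-kB targets, 2 rose and 8 fell by either adjustment, and the list was not called (median -0.36, adjusted p = 0.0901), except with no filter on dim probes (-0.16), under cyclic loess (-0.27) and with fry (adjusted p = 0.0112, where the alternatives within camera ranged from 0.0354 to 0.498). Nos2, the inducible nitric oxide synthase, rose by 2.21, whereas the neutrophil attractant Cxcl1 fell by 1.76 and the adhesion molecule Icam1 by 0.85. Of 28 interferon response genes, 2 rose and 5 fell by either adjustment, and the list was not called (median -0.18, or -0.11 without high density replicate 1 and -0.09 without regular density replicate 2, adjusted p = 0.408), except with fry (adjusted p = 0.0209). The interferon-induced Ifit3 had a log2 change of -1.06. Of 23 cholesterol synthesis genes, 3 rose and 3 fell by either adjustment, and the list was not called (median -0.11, or -0.06 without high density replicate 2, adjusted p = 0.546). Insig1, which restrains sterol synthesis, had a log2 change of -1.72. Of 19 angiogenic growth factors, 5 rose and 5 fell by either adjustment, and the list was not called (median -0.06, mean -0.08, adjusted p = 0.565), with an upward test direction and a median of 0.02 without regular density replicate 1.

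Of 23 matrix proteases and their inhibitors, 10 rose and 4 fell over all genes, and 11 rose and 5 fell adjusted over the list alone. The list was called higher (median 0.28, or 0.16 under median scaling, adjusted p = 0.00685, and adjusted p = 0.254 with an estimated correlation). The protease Mmp7 rose by 1.79, whereas the aggrecan-degrading protease Adamts5 fell by 1.90. Of 12 Notch pathway genes, 4 rose and 0 fell by either adjustment, and the list was called higher (median 0.37, or 0.25 under median scaling, adjusted p = 0.0196, and adjusted p = 0.254 with an estimated correlation). That call ended under quantile scaling (median 0.29, adjusted p = 0.0576, where the alternatives ranged from 0.00924 to 0.337), and the ligand Jag1 rose by 1.63. Of 14 YAP and TEAD targets, 5 rose and 1 fell over all genes, and 6 rose and 2 fell adjusted over the list alone. The list was called higher (median 0.44, adjusted p = 0.00467, and adjusted p = 0.254 with an estimated correlation), and in it the growth factor binder Crim1 rose by 1.60 and the matricellular Ccn1 by 0.80. Of 19 genes of the TGF-beta response, 5 rose and 2 fell over all genes, and 5 rose and 3 fell adjusted over the list alone. That list was called higher (median 0.25, or 0.12 under median scaling, adjusted p = 0.0196, and adjusted p = 0.254 with an estimated correlation), a call that ended without high density replicate 2 (median 0.23, adjusted p = 0.0673, where the alternatives ranged from 0.00706 to 0.0673). In it the basement membrane collagen Col4a1 rose by 1.51. Of 16 cell junction genes, 4 rose and 3 fell over all genes, and 5 rose and 4 fell adjusted over the list alone, and the list was not called (median 0.15, adjusted p = 0.247), except with fry (adjusted p = 0.0316). Its median was 0.22 without regular density replicate 1 and 0.05 without regular density replicate 2. The gap junction gene Gjb2 rose by 1.90, whereas Gja1, another gap junction gene, fell by 1.04.

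In all, 20 of the 32 tested lists were called, 13 higher and 7 lower, and 0 were called with limma's camera at an estimated correlation, where the lowest adjusted p was 0.220. For smooth muscle genes the estimated correlation was -0.044, under the preset 0.01, yet camera's unadjusted p went from 4.35e-16 to 0.0131. With 2 residual degrees of freedom, the 0 therefore does not decide whether correlation between genes undoes the list calls. With fry, which does not compare a list with other genes, 23 were called. Without any test, 468 features were higher and 146 lower by a fold of 2 or more in every pair of a high and a regular density array. Each of the other 2 ways to split the 4 arrays into pairs gave 0 such features. In those splits each side holds an array of both groups, so a feature that separates the groups cannot be counted. The 0 is therefore no measure of chance for such features. With the stricter filter on dim probes the count was 353.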

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

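Among the tests in this part, those of signal that varies between arrays, of actin paralogs and of a share of stromal cells, the pattern that selects olfactory genes, the ribosome term and cyclic loess were chosen only after the result was seen. The pattern was narrowed after a first look to leave out the oxidized LDL receptor Olr1. The rule that a list lying on the edge of its random range decides nothing was also set afterwards, on seeing the ribosomal protein genes.

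Signal outside the tested features was found in 3 places. The control sequence ERCC-00062_278 read 206 and 210 on the high density arrays and 105 and 121 on the regular density arrays before scaling, a log2 difference of 0.78 after scaling, and was the 1 of 53 control sequences above background on all 4 arrays. Of 13378 features left out as too dim, 517 lay above background on both high density arrays and on neither regular density array. The opposite held for 32 features. The background cutoff differed between arrays, at 34.5 and 28.2 before scaling at high density and 29.5 and 36.9 at regular density. How far this shaped the 2 counts was not tested.

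Smooth muscle genes rose at high density with a median log2 change of 2.82. Shared signal between actin paralogs as the whole cause of the list's rise was argued against, since the median without the actins was 2.31 over 12 genes. Most members are not actins and rose, so values already seen fixed this outcome. Whether shared signal raised the readings of the actin genes themselves was not tested. A trend with brightness alone was argued against too, since the median lay 2.98 above the middle of random lists of like brightness, whose central range was -0.25 to 0.26 around it. A higher share of stromal cells of all kinds as the whole cause was argued against, since the median change of stromal genes was 0.0333 of that of smooth muscle genes. That median is a weak measure of cell share, since 9 of 27 stromal genes rose and 6 fell. It was 0.09, above random lists of like brightness (-0.38 to -0.05), and 0.34 under quantile scaling, so a partial contribution is not excluded. What stays open, as a hypothesis, is that high density culture may favour cells that express contractile genes, either by a change in which cells grew or by a change within cells, which bulk RNA does not separate.

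Cell division genes rose while genes of several metabolic and stress lists fell, and brighter features fell as a whole, so brightness alone was tested for each list. Against the middle of random lists of like brightness, cell division lay 1.56 and DNA replication 0.537 above, and the response to low oxygen lay at -0.591, unfolded protein and amino acid stress at -0.381, lysosome at -0.357 and glycolysis at -0.337, all outside the central range of the random lists, which argues against brightness as the whole cause for these 6 lists. For ribosomal proteins it cannot be told apart from a change of their own, since their median lay at -0.0641 from the middle, on the edge of the random range. The wider Gene Ontology term structural constituent of ribosome (253 genes with many paralogs, median -0.42) lay below its own random range of -0.33 to -0.22. That range treats genes as independent, while paralogs can share signal, so it does not decide on brightness for that term. Cyclic loess, which removes trends with brightness, brought the median of the ribosomal protein list to -0.09. No biological explanation was tested for the lists outside their range.

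Olfactory receptor genes, whose products detect odours in the nose, were higher at high density: 48 of 117 rose and 0 fell, with a median of 0.55, and 29 to 40 rose and 0 fell under the other scalings. Tested with camera as a Gene Ontology term, they had adjusted p = 5.55e-13 with a preset correlation and adjusted p = 0.909 with an estimated correlation. Scaling between arrays was argued against, since under quantile scaling their median stayed 0.534 above that of all features, and brightness alone was argued against, since the median lay 0.522 above the middle of random lists of like brightness. The same genes also differed between arrays of one group, array 1 being above array 2 beyond random lists by 0.315 at high density and 0.173 at regular density. The medians, 0.298 and 0.165, lay above their random ranges (-0.07 to 0.04 and -0.08 to 0.05). Under a rule set after the result was seen, this met the pattern of non-specific signal that varies from array to array. That offset went with the replicate number in both groups, so its shared part cancels between groups, though the 2 values differ. The smaller value, 0.173, does not decide whether non-specific signal raised these genes at high density. Such signal and a change in the RNA of these genes both stay open.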

How the results depend on the processing

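The filters on the authors' probes and on negative controls, cyclic loess, leaving out olfactory receptor genes with unnamed probes, and leaving out arrays in the count over pairs of arrays were tests chosen only after seeing the data. The number of changed features, 4233, became 1971 without scaling, 868 with a fold of 2 as well, and 0 with an unmoderated test per gene in limma's linear model (3938 at an unadjusted p under 0.05), where 2 residual degrees of freedom are all that each gene has. Leaving out each array gave 2412 to 3976, with the lone array assumed to vary like the other group. With the replicate number as a block it became 7010, which included all 4233. It also brought Cdh5 (adjusted p = 0.0362), Hormad2 and the stromal and red cell lists past the threshold. The labels do not say that the number marks a shared batch, and the deviations of arrays with one number had a correlation of 0.37 across genes. The other alternatives gave 3108 to 4857. The share of calls that were higher was 42.1%, against 27.1% under median scaling (1204 higher and 3246 lower), 70.7% without scaling (1393 and 578), 60.1% under cyclic loess (2061 and 1367) and 73.2% with a fold of 2 (635 and 233). Called lists numbered 20, and 0 with an estimated correlation. Fry called 23, 14 higher and 9 lower, without endothelial cells and with stromal cells, inflammatory cytokines, the interferon response and cell junctions added. The count over pairs of arrays, 614, became 353 with the stricter filter on dim probes, and 678 to 910 without each array.

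Of the 115 tested genes named in the text, 111 were past the threshold, and 107 of these were past it under each of the 21 alternatives with limma's moderated test that covered them, including the 10 largest rises and the 10 largest falls. The unmoderated test, which called 0 features, is not among the 21. The exceptions were RT1-A1, RT1-CE7, Cd14 and Cxcr4. Most of these genes were named for a large change or a small p on the same arrays, so their share does not describe the other calls. Of all 4233 called features, 3360 were also called under quantile scaling and 1853 without scaling. Tbp, Hprt1, Gapdh, Ppia, Rplp0 and Pf4, which the naming rule allows, are not among the 115: they were left out after their direction was seen to reverse under some scalings. Results whose direction reversed were all uncalled, and the cause was not tested. For lists the direction is that of the test, so a median can keep its sign. Osteoclasts reversed under median scaling (median -0.23), with the authors' values and the series matrix (-0.080), with the negative control filter on 2 arrays and fry (-0.10), and without high density replicate 1 or regular density replicate 2 (leaving out each array gave -0.070 to -0.026). Chondrocytes reversed with fry (0.44), and angiogenic growth factors with fry (-0.056) and without high density replicate 2 (-0.062, the range over arrays being -0.062 to 0.022). Quantile scaling, the authors' values with the series matrix, and cyclic loess reversed oxidative phosphorylation (0.0083, 0.012 and 0.061), cholesterol synthesis (0.013, 0.0073 and 0.059) and reference genes (0.0058, 0.0058 and 0.043). The interferon response reversed with the stricter filter (-0.11). Vwf reversed under median scaling (-0.032) and without high density replicate 1 or regular density replicate 2 (range -0.40 to 0.59). Ptprc reversed under median scaling (-0.097) and without regular density replicate 2 (range -0.020 to 0.075). Hormad2 reversed without regular density replicate 2, the array with its bright spot (range -9.21 to 0.31). Genes under background on both arrays of a group allow only a lower bound of the fold.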

Other observations

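The Gene Ontology terms, the olfactory genes and the single spots in this part were chosen only after the results were seen, 10 terms having been picked for display from 1012 tested. Of the 1012 terms of 10 to 300 genes, 36 were called higher and 19 lower at the preset correlation. The terms described here had adjusted p = 0.909 with an estimated correlation.

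Of 51 focal adhesion genes, 25 rose and 3 fell (median 0.34, adjusted p = 1.86e-04), among them the heparan sulfate carrier Sdc1 (1.92), the actin-associated Pdlim7 (1.36) and caveolin Cav1 (1.26). Of 24 stress fiber genes, 16 rose and 1 fell (median 0.52, adjusted p = 8.16e-07), including the actin crosslinker Actn1 (1.49). Of 28 genes of muscle contraction, 17 rose and 1 fell (median 0.55, adjusted p = 5.74e-08), a term that shares genes such as Actg2 and Myh11 with the smooth muscle list. Structural genes of the extracellular matrix numbered 20, of which 10 rose and 2 fell (median 0.47, adjusted p = 0.00944), with the collagens Col5a3 (1.59) and Col18a1 (1.06). Of 35 genes of microtubule-based movement, 20 rose and 0 fell (median 0.47, adjusted p = 3.92e-07), among them the mitotic motors Kif18b (1.85) and Kif11 (1.56).

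Of 25 genes of the MHC class I complex, 0 rose and 18 fell (median -0.49, adjusted p = 3.34e-05). Many of them are related RT1 genes, whose probes may bind each other's RNA, so the 18 falls may not be separate changes. The antibody receptor Fcgrt had a log2 change of -0.75, the class I chain RT1-CE7 one of -0.62 and RT1-A1 one of -0.61. The calls of RT1-A1 under quantile scaling (-0.31) and of RT1-CE7 without scaling (-0.51) ended. Of 16 glutathione transferase genes, 0 rose and 7 fell (median -0.37, adjusted p = 0.0112), with Gstm7 at -1.54 and Gstp1 at -0.76. Of 253 genes for structural constituents of the ribosome, 1 rose and 152 fell (median -0.42, adjusted p = 5.55e-13), and of 30 glycolysis genes, 3 rose and 17 fell (median -0.52, adjusted p = 0.0531). Outside the naming rule and chosen after their values were seen, the cytotoxic protease Gzmc rose by 1.99 and the pigment cell gene Mlana, whose protein partners Pmel, had a log2 change of -2.58. The largest olfactory changes were those of Or5p66 (2.69) and Or13p5 (2.59).

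Some spots were bright on 1 array alone, by at least 4 log2 above the other 3 arrays: 12 on high density replicate 1, 0 on high density replicate 2, 2 on regular density replicate 1 and 2 on regular density replicate 2. Hormad2 read 15.15 log2 on regular density replicate 2, 9.02 above the other arrays, while the spots around it had an excess of -0.60. It had a fitted change of -4.45 (adjusted p = 0.243), which was 0.31 without that array and past the threshold without any 1 of the other 3 (-9.21 to -4.26). Olig3 on high density replicate 1 had an excess of 11.86, and Kdm6b on regular density replicate 2 one of 8.69.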
